A study of Mus musculus with 24 samples.

How the data were processed

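The libraries were made from total RNA of whole mouse back skin with a stranded kit, per the labels, and each library came from RNA pooled from 2 to 4 animals. The mice were male C57BL/6NCrl, a common inbred laboratory strain, about 8 weeks old and in telogen, the resting stage of the hair cycle, per the labels. They were kept in 12 h of light and 12 h of darkness, with lights on at ZT0 (ZT is the time in hours since lights on). The 3 feeding regimes, called ED, MD and EN in the labels, gave food from ZT0 to ZT4, from ZT5 to ZT9 and from ZT12 to ZT16. Each of the 3 groups had 8 libraries, 1 at each sampling time from ZT0 to ZT28 in steps of 4 h, so that ZT24 and ZT28 repeat the clock times of ZT0 and ZT4 on the second day. No group had more than 1 library at a sampling time, and the error in each test comes from the departure of the 24 libraries from the fitted model. Whether pools taken at different times were made from separate sets of mice is not given in the sources used here, so p-values measure the spread between these pools.

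The deposited count table holds whole-number read counts per gene model, not normalized, with separate rows for exon, intron and antisense reads of each of 31872 models, per the file headers. TopHat2, SAMtools and HOMER and the mouse build mm10 are named in the submitters' processing notes, without versions. The program that made the counts and its treatment of reads matching several places are not given in the sources used here. For this reason values of genes with near-identical copies are uncertain, which here concerns the H2 genes, the globins, Mt1 and Mt2, Hspa1a and Hspa1b, the ribosomal proteins and the Scd genes. A deposited second table holds RPKM values made with cqn, per the file name, and its values are on a linear scale with upper ends that are equal between libraries within a row type. Every column matched the title of 1 library, and 0 columns belonged to no sample. Exon rows were used for all comparisons, and intron and antisense rows for the closing observations. Of rows sharing a symbol, the row with the highest total was kept, which left 29758 symbols and left out 2114 rows. A total of 9289 models had no exon count. Gene coordinates are those of the annotation of GRCm38.p6, the same sequence as mm10, matched by symbol.

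Genes were kept by the filterByExpr function of edgeR by feeding group with its defaults (a minimum count of 10 and a minimum total of 15), which left 15719 genes. Counts were scaled by TMM, and log2 CPM was computed with a prior count of 2. The tests used edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, with DESeq2 1.42.0 as an alternative. All adjusted p-values of single genes are from the quasi-likelihood F test of edgeR with Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. A single model over the 24 libraries had a mean, a cosine and a sine term with a period of 24 h for each feeding group (15 residual degrees of freedom). From it came the test of rhythm in each group, the test of a different rhythm between groups for each of 3 pairs, and the test of a different mean level, which is the mean of the fitted curve. Amplitudes (from mean to peak, log2) and peak times with standard errors are from least squares on log2 CPM in the same model. Amplitudes and fold changes are given with their standard error from these fits, and levels with their SD.

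The phase of the clock list was compared between groups as the circular mean of the difference in peak time over members with a rhythm in both groups, with a jackknife error over the 8 sampling times. Its p is from an exact two-sided permutation test over 256 swaps of group labels within sampling times, adjusted over 3 pairs. The statistic was the summed squared difference of cosine and sine terms over all measured members of the list. It answers to a difference in amplitude as well as in phase. The smallest p those swaps can give is 0.00781. Libraries taken 3 to 8 h after food was opened (7 libraries) were compared with those taken 19 to 24 h after it was last opened (9 libraries), in a model with feeding group, time of day and a class of 11 to 16 h (8 libraries), with 14 residual degrees of freedom. Genes with a rhythm in at least 1 group were tested for departure from a rhythm shared by the groups, once with time as ZT and once as hours since food was opened. A gene that departed from the shared food time rhythm and not from the shared ZT rhythm was counted as following light, and the opposite as following food.

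The 33 gene lists were core clock and clock output, nucleotide excision repair, p53 and UV damage response, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, fasting and fatty acid oxidation, FOXO and amino acid shortage, glucocorticoid response, heat shock and temperature, endoplasmic reticulum chaperones, ribosomal proteins and ribosome biogenesis, DNA replication and S phase, mitosis, interferon response, glycolysis, oxidative phosphorylation, antioxidant and NRF2 targets, immediate early genes, and markers of basal keratinocytes, differentiated keratinocytes, hair shaft and anagen follicle, sebocytes, adipocytes, skeletal muscle, dermal fibroblasts, endothelium and pericytes, melanocytes, macrophages and Langerhans cells, T and B lymphocytes, neutrophils and mast cells, red blood cells, nerve and Schwann cells, and thermogenic adipocytes. The lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Of the list genes, 15 had no row of their own symbol and 6 of these were matched by an older symbol (Ciart as Gm129). Lists were tested for the 3 mean level contrasts and the food contrast with camera (limma voom) at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether a list's genes move on balance one way, each adjusted over 132 list tests. Numbers of rhythmic or differently rhythmic members were tested against the other genes with Fisher's exact test, adjusted over the lists and these comparisons. Fisher's test takes genes as independent, although members of a list share the same pools and can move together, so its p-values can be far too small. In no contrast did a list call hold with an estimated correlation.

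Genes were named by a fixed rule. It took each clock list member, the 5 highest and 5 lowest fold changes of each mean level contrast, and the 12 highest and 12 lowest of the food contrast, among genes past the threshold with a mean log2 CPM of at least 1. It also took the 5 genes with the smallest p of each test of different rhythms, the 5 rhythmic genes with the largest amplitude in each group, the 6 genes each following light and food with the smallest p, and up to 4 members with the smallest p of every other list and comparison. In the nucleotide excision repair list, Xpa, Xpc, Ddb2 and the Ercc genes were named whatever their p. Some genes that this rule takes are not reported here. Genes outside the clock list were taken for the parts on rhythms, and predicted genes and small RNAs were passed over by name, which did not cover all of them (such as the vault RNA Vaultrc5). Gene names given beside these as members of the hair list or as Hox genes were chosen after their values were seen.

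The tests of single genes were run on simulated counts for 15719 genes, with 100 genes changed at each of 2 sizes, for the group or pair named below. The clock phase comparison, the amplitude ratios and the list tests were not simulated. At a log2 amplitude or fold change of 0.5 and 1, the test of rhythm in ED recovered 63% and 97% of the changed genes. The test of different rhythms between MD and ED, with peaks 6 h apart, recovered 58% and 98%, the test of mean level between MD and ED 78% and 98%, and the food contrast 69% and 99%. Genes made to follow light were called so in 75% and 100%, and genes made to follow food in 80% and 96%, with 0 called for the other frame in either case. False calls numbered from 0 to 10 among 15519 unchanged genes. The changed genes were drawn from those with a mean of at least 2 CPM. Each gene was simulated apart from the others, so these rates do not cover variation between libraries that many genes share. Exon counts per library ranged from 13222667 to 26316851. Libraries of the same clock time on both days differed beyond counting noise (chi-square per degree of freedom 14.0 to 59.2), so that each was kept as a library of its own.

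Alternatives were the size factors of DESeq2, no filter on low counts, the DESeq2 test, limma on the deposited RPKM values (log2 after adding 0.1), skeletal muscle and adipocyte list means as covariates, each library left out, no second day, the L number of the library code as a random block, each group fitted alone, an added harmonic of 12 h, sampling time as a replicate block, other forms of the food contrast, stricter thresholds for following light or food, other summaries of the clock phase, and rows sharing a symbol kept. Chosen after seeing the data were the fits without the ED ZT24 and EN ZT0 pools, without small structural RNA rows (689 rows), without the MD libraries, on intron rows, and for the clock phase with tissue covariates. Numbers 1 to 8 of the libraries in each group stand for sampling times, not for shared animals.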

Results

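Gene expression was measured by RNA sequencing in whole back skin of mice that could eat only during a daily window of 4 h. The title of the series places the data in a study of how the time of feeding moves the clock of the skin and bears on DNA damage by UVB light. No library here carries a label of irradiation. There were 24 libraries, each from a pool of mice, in 3 groups of 8 named ED (food from ZT0 to ZT4, after lights on), MD (ZT5 to ZT9, in the middle of the light phase) and EN (ZT12 to ZT16, after lights off). Total exon counts per library averaged 16976565 ± 2677812 in ED, 20098335 ± 1842617 in MD and 17104698 ± 3893304 in EN (SD, n = 8 each). They ranged from 13222667 to 26316851. There was 1 pool per group and sampling time. Pools of the same clock time on both days differed by a median of 0.12 to 0.25 on the log2 scale across genes.

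The clock of the skin peaked at a different time of day in each feeding group. Dbp, a transcription factor driven directly by the clock (uc009gws.2; chromosome 7, 45705100 to 45710203, mm10), peaked at ZT 12.4 ± 0.382 h in ED, ZT 4.11 ± 0.336 h in MD and ZT 9.02 ± 0.241 h in EN (standard error, 8 pools each). Nr1d1, which encodes the clock repressor REV-ERBα (chromosome 11, 98767932 to 98775377), peaked at ZT 9.38 ± 0.339 h, ZT 1.44 ± 0.343 h and ZT 5.96 ± 0.238 h in the same order. Arntl, which encodes the activator BMAL1 (chromosome 7, 113178471 to 113314126), peaked at ZT 0.847 ± 0.566 h in ED, ZT 17.5 ± 0.550 h in MD and ZT 21.6 ± 0.414 h in EN. Per3, a period gene of the negative limb, peaked at ZT 14.2 ± 0.333 h, ZT 5.65 ± 0.317 h and ZT 10.5 ± 0.223 h. Cry1, which encodes a late repressor of the clock, followed at ZT 19.3 ± 0.703 h, ZT 11.8 ± 0.424 h and ZT 16.5 ± 0.321 h.

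**Figure D1:**
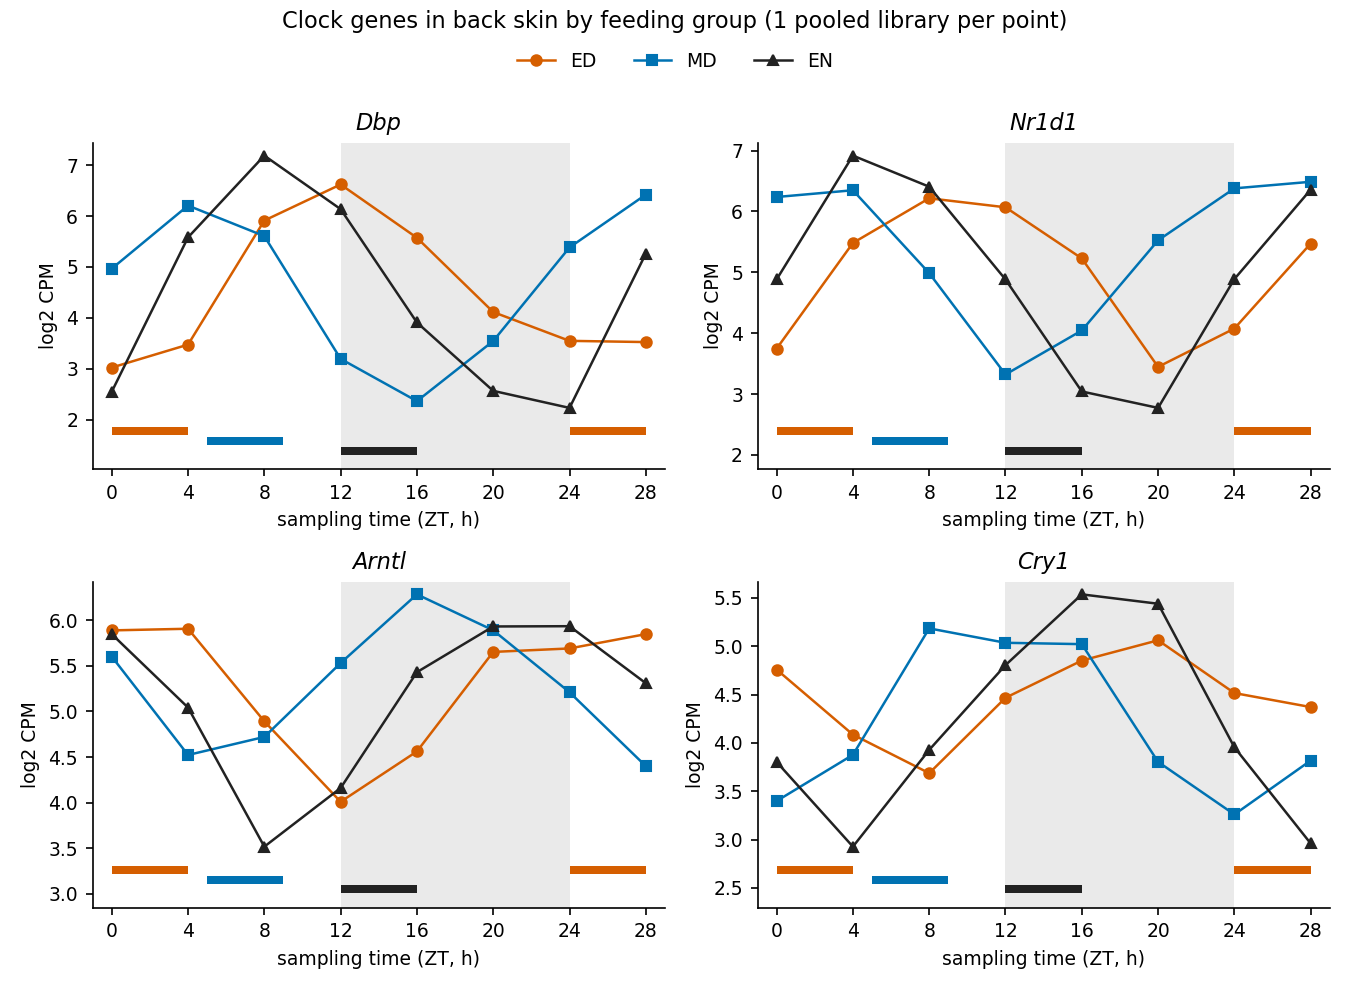
Expression (log2 CPM) of Dbp, Nr1d1, Arntl and Cry1 against sampling time (ZT, h) in ED, MD and EN, with 1 pooled library per point, lines joining the points of a group, grey shading for darkness and coloured bars for each group's food window. The curves keep their order within each group but are shifted between groups, with fitted Dbp peaks at ZT 12.4 (ED), ZT 9.02 (EN) and ZT 4.11 (MD).

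Of the 21 clock genes measured, 11 were rhythmic in ED, 13 in MD and 18 in EN (19, 18 and 20 adjusted over the list alone). Each of these numbers exceeded that of other genes (Fisher's exact test, which takes genes as independent, adjusted p = 1.41e-17, 1.68e-20 and 3.54e-31). Peak times were compared over the members rhythmic in both groups of a pair. The difference was -7.72 ± 0.360 h for MD minus ED (jackknife standard error over 8 times; 10 genes, -8.51 to -7.06 h). It was -3.34 ± 0.587 h for EN minus ED (11 genes, -4.20 to -2.77 h) and 4.32 ± 0.458 h for EN minus MD (13 genes, 3.10 to 5.11 h). The exact permutation test over all 21 members, which answers to amplitude as well as to phase, gave p = 0.00781 in each pair. This is the smallest that swapping labels within times can give (adjusted p = 0.00781). Without ZT8 in either group the difference for EN minus MD was 4.46 h and the test did not pass (exact permutation p = 0.0781). The start of food differed by 5 h, 12 h and 7 h in the same pairs, and 12 h later equals 12 h earlier on a daily cycle. The rhythm itself differed for 14 of 21 members between MD and ED, 10 between EN and ED and 11 between EN and MD (19, 17 and 20 adjusted over the list alone). For Dbp the adjusted p was 5.60e-09, 6.1e-05 and 2.05e-07. Mean amplitudes over the shared members were 1.54 times as high in EN as in ED, 1.33 times as high in EN as in MD and 1.11 times as high in MD as in ED. None of these ratios passed the adjustment (exact permutation p = 0.0391, 0.305 and 0.75, adjusted p = 0.117, 0.457 and 0.75). For Dbp the amplitudes were 1.75 ± 0.166 in ED, 1.97 ± 0.167 in MD and 2.60 ± 0.176 in EN (log2).

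**Figure D2:**
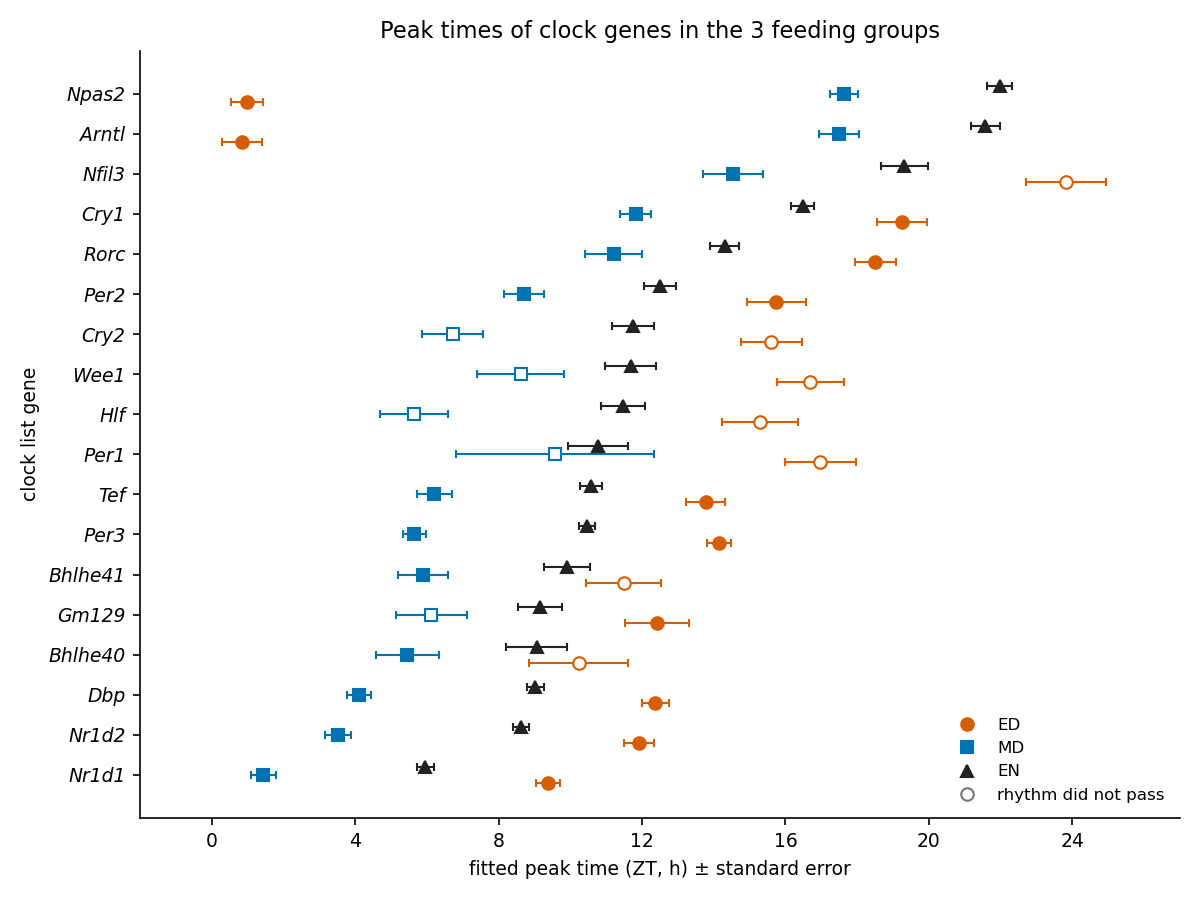
Fitted peak time (ZT, h) ± standard error of the 18 clock list genes rhythmic in at least 1 feeding group, with a symbol per group and open symbols where the rhythm did not pass the test. Peaks of Dbp, Nr1d1, Per3 and Arntl come earliest in MD and latest in ED, with mean differences of -7.72 h (MD minus ED) and -3.34 h (EN minus ED).

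Rhythms outside the clock list were looked for within each feeding group. In ED, the rhythmic genes included some of fat and glycogen metabolism and of cell division. Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1 (chromosome 8, 35375694 to 35388139), had a log2 amplitude of 1.67 ± 0.368 and a peak at ZT 5.22 (adjusted p = 0.0177). Scd2, a stearoyl-CoA desaturase (chromosome 19, 44293676 to 44306864), had 1.16 ± 0.201 and a peak at ZT 8.08 (adjusted p = 0.00292). Tshr, the thyrotropin receptor gene, and G0s2, which encodes an inhibitor of the lipase ATGL, had amplitudes of 1.15 ± 0.198 and 1.14 ± 0.268. Ccnb1, the cyclin B1 gene of mitotic entry (chromosome 13, 100778739 to 100786486), peaked at ZT 23.2 with an amplitude of 0.92 ± 0.123 (adjusted p = 8.06e-04). In MD, the largest amplitudes were those of Myh7 and Myl2, genes of slow and cardiac muscle. They were 2.87 ± 0.402 (peak ZT 14.6, adjusted p = 0.00134) and 2.01 ± 0.419. Myh7 was low in MD, with a mean CPM below its SD (given with the mean levels below), so its amplitude is uncertain. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090979 to 29100722), had an amplitude of 0.55 ± 0.0682 with a peak at ZT 13.2 in MD (adjusted p = 2.50e-04). In EN, Spon2 and Adamts4, genes of extracellular matrix proteins, reached 1.87 ± 0.297 (peak ZT 22.8) and 1.60 ± 0.223 (peak ZT 23.0).

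In all, 113 genes were rhythmic in ED, 148 in MD and 166 in EN, which is 0.72%, 0.94% and 1.06% of the 15719 genes tested. Of these, 20 were rhythmic in all 3 groups, 46 in exactly 2 and 275 in exactly 1. Overlaps were 25 genes for MD and ED, 35 for EN and ED and 46 for EN and MD, where independent lists would share 1.06, 1.19 and 1.56. Fbn1, the fibrillin gene of elastic microfibrils (chromosome 2, 125300594 to 125506485), was rhythmic in each group. Its amplitudes were 0.56 ± 0.0892 in ED, 0.95 ± 0.0951 in MD and 0.91 ± 0.0888 in EN, with peaks at ZT 3.24, ZT 21.4 and ZT 1.23. A rhythm that passed in one group and not in another was not thereby shown to differ, and the tests of the difference are given further on. Without the second day the counts were 24, 78 and 64, and with each group fitted alone they were 74, 23 and 298.

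Mitosis genes had 17 of 25 members rhythmic in ED (24 adjusted over the list alone, Fisher's exact test, adjusted p = 9.44e-30). In EN 4 of 25 passed (18 adjusted over the list alone, adjusted p = 0.00177) and in MD 1 of 25 (7 adjusted over the list alone, adjusted p = 0.782). Fisher's test takes the members as independent, although they were measured in the same pools, so these p-values can overstate the evidence. Cenpf, a kinetochore gene, had an amplitude of 1.04 ± 0.145 in ED with a peak at ZT 23.5, and Cdc20, an activator of the anaphase-promoting complex, 0.78 ± 0.124 in EN with a peak at ZT 23.8. The mitosis list mean was highest in the ED ZT24 pool, one of a pair of pools with high hair keratins. Without that pool and the EN ZT0 pool 8 members passed in ED and 2 in EN (22 and 11 adjusted over the list alone). Of DNA replication and S phase genes none of 26 passed edgeR's test in any group, also when adjusted over the list alone (3, 7 and 2 at an unadjusted p under 0.05 in ED, MD and EN; DESeq2 0, 1 and 1). Without the same pair of pools, 8 passed in ED and 1 in EN adjusted over the list alone, and 0 over all genes. Fatty acid and triglyceride synthesis had 7 of 25 rhythmic members in ED (10 adjusted over the list alone, adjusted p = 8.53e-09). Acly, the ATP citrate lyase gene, was among them, at 0.74 ± 0.152 with a peak at ZT 8.86. In MD 1 and in EN 2 of these 25 passed (5 adjusted over the list alone in each). Without the ED ZT24 and EN ZT0 pools 3 passed in ED and 1 in EN (12 and 3 adjusted over the list alone). Glucocorticoid response genes were rhythmic in EN, at 4 of 19 (16 adjusted over the list alone, adjusted p = 6.38e-04). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, was at 1.27 ± 0.336 and a peak at ZT 12.9 (adjusted p = 0.0308). Without both pools 1 of the 19 passed in EN (16 adjusted over the list alone). Hair shaft and anagen follicle genes passed in EN at 2 of 8 (7 adjusted over the list alone, adjusted p = 0.0357). Their amplitudes, 3.06 ± 1.60 for Krt71 and 2.59 ± 1.43 for Krt27, rest on the EN ZT0 pool. Without it and the ED ZT24 pool 0 of 8 passed by edgeR, and with all pools 0 passed by DESeq2 and by limma on RPKM values.

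Differences in rhythm between groups were tested for each pair of feeding groups. Between MD and ED, Fbn1 peaked at ZT 21.4 against ZT 3.24 (adjusted p = 2.39e-04) and Spon2 at ZT 18.6 against ZT 2.50 (adjusted p = 0.00272). Cdkn1a had its amplitude of 0.55 in MD against 0.18 ± 0.0681 in ED (adjusted p = 8.64e-04). Between EN and ED the gene with the smallest p outside the clock was Cyp2e1, which encodes a cytochrome P450 that rises in fasted liver (chromosome 7, 140763819 to 140774990). Its amplitude was 0.96 ± 0.123 with a peak at ZT 12.9 in EN and 0.45 ± 0.127 with a peak at ZT 23.4 in ED (adjusted p = 1.06e-04). Scd2 peaked at ZT 21.1 in EN against ZT 8.08 in ED (adjusted p = 5.07e-04), and Sdf2l1, an endoplasmic reticulum chaperone gene, at ZT 18.7 against ZT 7.36 (adjusted p = 0.00460). Between EN and MD, Cyp2e1 peaked at ZT 12.9 against ZT 4.19 (adjusted p = 8.5e-05) and Gsta3, a glutathione transferase gene, at ZT 16.6 against ZT 9.48 (adjusted p = 0.00255).

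Counts of differently rhythmic genes were 55 for MD and ED, 63 for EN and ED and 55 for EN and MD (1841, 1829 and 2000 at an unadjusted p under 0.05). The clock list held 14, 10 and 11 of them. Heat shock genes differed at 2 of 20 members between MD and ED and 3 of 20 between EN and ED (12 and 15 adjusted over the list alone, adjusted p = 0.0276 and 9.77e-04). Hspa8, a cytosolic chaperone gene, was among them, with peaks at ZT 5.09 in ED, ZT 12.4 in MD and ZT 16.9 in EN. Between EN and ED, endoplasmic reticulum chaperones differed at 4 of 18 (14 adjusted over the list alone, adjusted p = 1.27e-05). Fatty acid and triglyceride synthesis differed at 5 of 25 (12 adjusted over the list alone, adjusted p = 8.92e-07), with Thrsp, a gene of lipogenic tissues, peaking at ZT 16.1 in EN against ZT 7.21 in ED. Mitosis genes showed no different rhythm by edgeR over all genes in any pair, while 11 of 25 passed between MD and ED when adjusted over the list alone. With sampling time as a block the counts were 71, 136 and 95, and without the second day 16, 20 and 22.

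Whether a rhythm kept its time against the light cycle or against food was tested in both time frames. Ccnb1 peaked near the end of darkness in each group (ZT 23.2, ZT 20.5 and ZT 0.335 in ED, MD and EN), and departed from a shared rhythm against food (adjusted p = 5.4e-05) but not against ZT (adjusted p = 0.139). Other mitosis genes such as Cenpf (ZT 23.5, 21.5 and 23.6) and Aspm, a spindle gene (ZT 23.0, 21.8 and 0.00676), did likewise. Cyp2e1 peaked close to the next opening of food, at 23.4 h after it in ED, 23.2 h in MD and 0.928 h in EN, and departed from a shared ZT rhythm (adjusted p = 1.7e-05) but not from a shared food rhythm (adjusted p = 0.140). Scd2 peaked 8.08, 7.69 and 9.07 h after food was opened, Gsta3 5.79, 4.48 and 4.59 h, and Pnpla3, a lipid droplet gene, 5.84, 7.33 and 6.83 h.

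**Figure D3:**
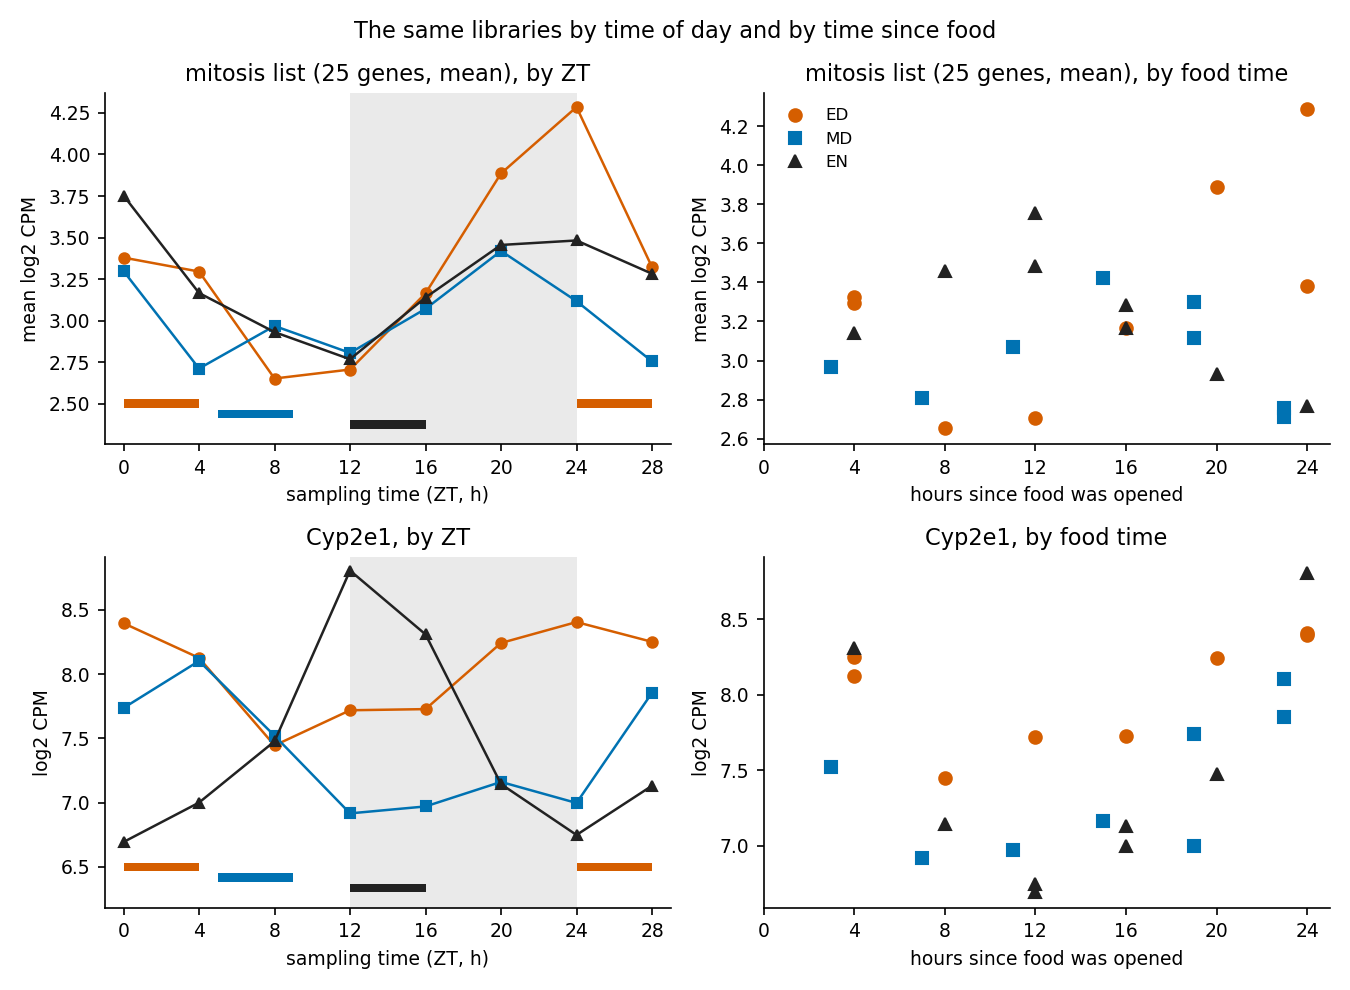
Mean of the 25 mitosis genes and Cyp2e1 (log2 CPM) against sampling time (ZT, h; left, with grey for darkness and coloured bars for food) and against hours since food was opened (right), with 1 pooled library per point in ED, MD and EN. The mitosis list has its high values around ZT20 to ZT24 in each group, whereas Cyp2e1 lines up when time is counted from food, with peaks at 23.4, 23.2 and 0.928 h.

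Of the 341 genes rhythmic in at least 1 group, 58 followed food, 92 followed light, 61 departed from both frames and 130 from neither. Of 25 mitosis genes 17 followed light (Fisher's exact test among rhythmic genes, which takes genes as independent, adjusted p = 2.18e-09) and the other 8 were not rhythmic. Without the ED ZT24 and EN ZT0 pools 9 followed light. For these genes a departure from a shared ZT rhythm did not pass, which does not show that none exists. Over 7 mitosis genes rhythmic in both MD and ED (adjusted over the list alone), peaks differed by -2.29 ± 0.641 h (MD minus ED). Of 25 fatty acid and triglyceride synthesis genes 5 followed food (adjusted p = 0.0642), and 3 without both pools. The 21 clock genes mostly departed from both frames, at 15 members. Per1, Bhlhe40 and Bhlhe41 were counted as following light, although their peaks in MD differed from those in ED by -7.40, -4.78 and -5.60 h. Their departure from a shared ZT rhythm did not pass. Clock, Rora and Usp2 were not rhythmic in any group. With the second day left out, 17 genes followed food and 38 followed light.

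Pools taken 3 to 8 h after food was opened were compared with pools taken 19 to 24 h after it, with time of day as a term of the model. This term is the same in each feeding group, so any rhythm whose phase differs between groups can enter the contrast. The calls below are therefore not of food alone. Clock times were not matched throughout, as ZT0 and ZT24 have no pool after food and ZT16 has none before it. After food, Ppp1r3b rose by 2.58 ± 0.262 on the log2 scale (29.4 ± 13.9 against 5.87 ± 3.60 CPM, SD, n = 7 and 9; adjusted p = 1e-05) and Scd2 by 1.64 ± 0.151 (adjusted p = 7e-06). Pck1, the gluconeogenic and glyceroneogenic enzyme gene (chromosome 2, 173153073 to 173159274), changed by -2.25 ± 0.225 (33.7 ± 17.7 against 122.5 ± 80.0 CPM; adjusted p = 1e-05). Angptl4, a lipase inhibitor gene induced by fasting, changed by -1.37 ± 0.189, and Txnip, which encodes a brake on glucose uptake, by -1.29 ± 0.169. Myod1, a muscle transcription factor gene, rose by 1.92 ± 0.387. In total 762 genes differed, 376 higher and 386 lower after food, and 358 and 362 of these had the same sign in each of the 3 groups taken alone. These signs are from plain means without a term for time of day. The genes were called on the same pools, so the agreement is not separate support. Each of the genes named in this paragraph had its direction in 3 of 3 groups.

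Among the lists, chaperone and lipid synthesis genes rose after food and glucocorticoid response genes fell. Endoplasmic reticulum chaperones rose at 13 of 18 members and fell at 0 (15 adjusted over the list alone), with Sdf2l1 at 1.13 ± 0.120 and Hspa5, which encodes BiP, at 0.83 ± 0.115. The list had adjusted p = 5.57e-16 by camera, and adjusted p = 0.239 with an estimated correlation. Cholesterol synthesis and uptake rose at 8 of 25 (12 adjusted over the list alone), with Mvd at 0.58 ± 0.0980. Its camera call had adjusted p = 3.59e-09, and adjusted p = 0.386 with an estimated correlation. Fatty acid and triglyceride synthesis rose at 9 of 25 (11 adjusted over the list alone), with Acly at 0.88 ± 0.121 and Mlxipl, which encodes the carbohydrate sensor ChREBP, at 0.64 ± 0.0993. For this list adjusted p was 2.64e-08, and adjusted p = 0.386 with an estimated correlation. Heat shock genes rose at 10 of 20 and fell at 2 (17 adjusted over the list alone). By camera the list had adjusted p = 3.59e-09, and adjusted p = 0.386 with an estimated correlation. Both that fell, Cirbp (-0.94 ± 0.163) and Rbm3 (-0.69 ± 0.111), are cold-induced RNA-binding protein genes. Glucocorticoid response genes fell at 11 of 19 and rose at 1 (15 adjusted over the list alone), with Sgk1 at -0.69 ± 0.0902 and Nfkbia at -0.67 ± 0.0667. Camera gave adjusted p = 2.49e-14, and adjusted p = 0.371 with an estimated correlation.

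**Figure D4:**
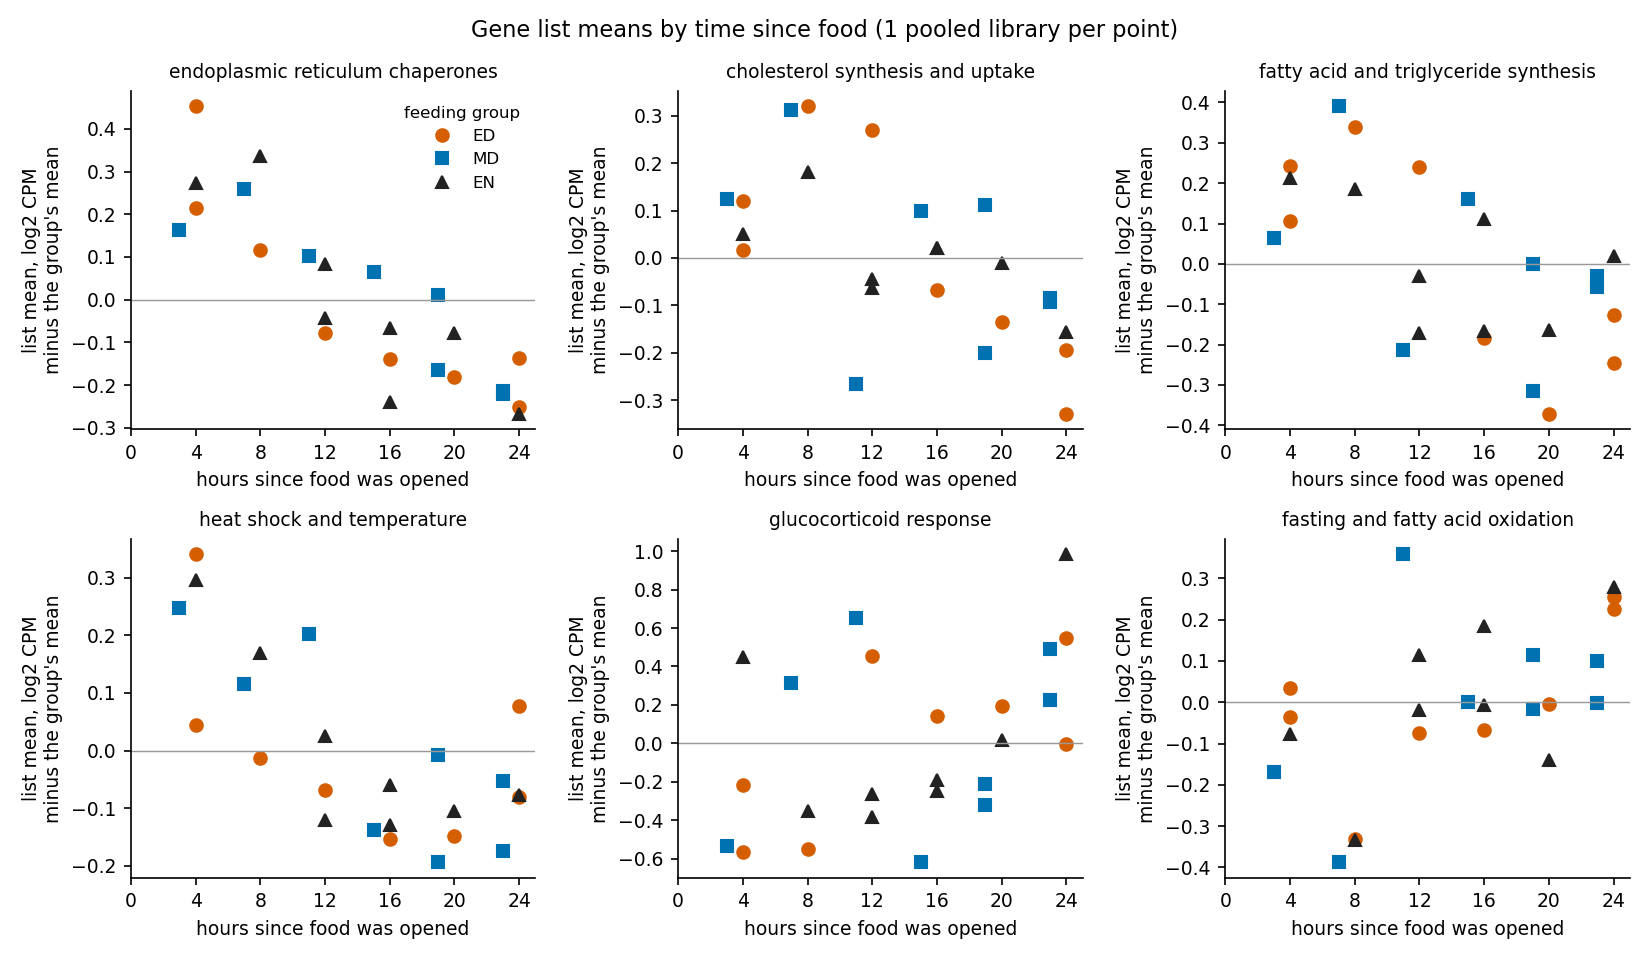
Mean log2 CPM of 6 gene lists, minus the mean of the same list in the feeding group, against hours since food was opened, with 1 pooled library per point in ED, MD and EN. Endoplasmic reticulum chaperones, of which 13 of 18 passed, are high at 3 to 8 h after food in each group. The glucocorticoid response list, of which 11 of 19 passed as lower after food, is also high at 7 and 11 h in MD and at 4 h in EN.

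Members of other lists moved as well. Fasting and fatty acid oxidation genes fell at 4 of 27 (6 adjusted over the list alone), with Cpt1a, the gatekeeper of mitochondrial fatty acid uptake, at -0.91 ± 0.0961. The fasting list had adjusted p = 0.0012 by camera, and adjusted p = 0.583 with an estimated correlation. FOXO and amino acid shortage genes fell at 7 of 26 and rose at 1 (17 adjusted over the list alone), with the insulin receptor substrate gene Irs2 at -0.86 ± 0.152 and Atf4 at 0.30 ± 0.0719. This call had adjusted p = 0.00138, and adjusted p = 0.555 with an estimated correlation. Glycolysis rose at 3 of 19 and fell at 1 (10 adjusted over the list alone), with the glucose transporter gene Slc2a1 at 0.34 ± 0.0736 (8 members by DESeq2 and 7 by limma on RPKM values). Glycolysis had adjusted p = 3.49e-05, and adjusted p = 0.555 with an estimated correlation. Adipocyte genes fell at 3 of 14 (4 adjusted over the list alone), with Lipe, the hormone-sensitive lipase gene, at -0.77 ± 0.120. The adipocyte list had adjusted p = 0.00295, and adjusted p = 0.583 with an estimated correlation. Immediate early genes fell at 4 of 20 (6 adjusted over the list alone; adjusted p = 4.87e-05, adjusted p = 0.431 with an estimated correlation). The clock list rose at 3 and fell at 10 of 21 (18 adjusted over the list alone; adjusted p = 4.52e-07, adjusted p = 0.239 with an estimated correlation). Dbp changed by -2.29 ± 0.480, lower in 2 of 3 groups. The model gives time of day the same effect in each feeding group, which the clock genes did not follow. The p53 and UV damage response changed at 5 of 18 members, 4 higher and 1 lower (9 adjusted over the list alone; camera, adjusted p = 0.274). Oxidative phosphorylation and thermogenic adipocyte genes each rose at 1 member (of 29 and 7; 1 and 3 adjusted over the list alone). They had adjusted p = 8.07e-05 and 0.0198 by camera, and adjusted p = 0.657 and 0.371 with an estimated correlation. Differentiated keratinocyte genes rose at 1 of 16, and interferon response, basal keratinocyte, sebocyte and nerve genes fell at 1 each (of 26, 10, 14 and 10). Skeletal muscle, macrophage, and neutrophil and mast cell genes had no member past edgeR's test (7 of 20, 0 of 14 and 3 of 9 adjusted over the list alone). Camera called these lists (adjusted p = 4.38e-07, 8.54e-05 and 0.0013, adjusted p = 0.555, 0.555 and 0.539 with an estimated correlation). The muscle list mean moved by 0.56 in ED, 0.11 in MD and -0.04 in EN. No member passed among ribosomal protein, S phase, mitosis, antioxidant, hair, fibroblast, endothelium, melanocyte, lymphocyte and red blood cell genes by edgeR. Leaving out pools taken at the hour of opening gave 344 genes, and muscle and adipocyte list means as covariates 177.

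Nucleotide excision repair, the pathway that removes UV photoproducts, was examined because the title of the series names DNA damage. Xpa, the gene of its damage verification factor (chromosome 4, 46175220 to 46196344), had amplitudes of 0.16 ± 0.150 in ED, 0.12 ± 0.152 in MD and 0.40 ± 0.151 in EN (adjusted p = 0.789, 0.788 and 0.467). Its change after food was -0.40 (adjusted p = 0.141), and that of Xpc, a gene of damage recognition, was -0.22 (adjusted p = 0.0899). None of the 32 members passed edgeR's test of rhythm in ED, MD or EN (3, 4 and 0 at an unadjusted p under 0.05; DESeq2 1, 0 and 0). Nor did any pass for different rhythms (5, 4 and 1 unadjusted; DESeq2 0 in each) or after food (5 unadjusted; DESeq2 1). By limma on RPKM values 0 passed in each of these tests. In mean level 2 were higher and 3 lower in MD than in ED (4 adjusted over the list alone) and 5 higher and 5 lower in EN than in MD (4 in total by limma on RPKM values). In the p53 and UV damage response, Cdkn1a was rhythmic in MD and EN and Ccng1, a cyclin G1 gene, in ED. Without the ED ZT24 and EN ZT0 pools 0 of 18 members of this list passed in ED, 1 in MD and 0 in EN. Adjusted over the list alone 2 then passed in ED and 1 in EN.

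The mean level over the day was compared between groups, and MD stood apart. Skeletal muscle genes rose in MD against ED at 17 of 20 members (18 adjusted over the list alone). The muscle list had adjusted p = 2.63e-11 by camera, and adjusted p = 0.386 with an estimated correlation. Among them the nebulin gene Neb rose by 1.05 ± 0.161, the titin gene Ttn by 1.00 ± 0.162 and the desmin gene Des by 0.89 ± 0.148 (log2; 8 of 8 times). Ankrd1, a stretch-responsive muscle gene (chromosome 19, 36111965 to 36119844), rose by 2.19 ± 0.458 (24.0 ± 15.6 against 5.37 ± 3.73 CPM, SD, n = 8 each; adjusted p = 0.00193). Flnc and Xirp1, genes of muscle cell junctions, rose by 1.49 ± 0.226 and 1.93 ± 0.361. The slow muscle genes Myh7 and Myl2 went the other way, with Myh7 (chromosome 14, 54970684 to 54994626) at -3.91 ± 0.398 (2.85 ± 4.21 against 20.9 ± 7.35 CPM; adjusted p = 4.31e-06) and Myl2 at -3.14 ± 0.425. Defb8, a defensin gene, and Vaultrc5, a vault RNA, differed by -2.65 ± 0.458 and -2.55 ± 0.222.

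Adipocyte genes fell in MD at 11 of 14 members (11 adjusted over the list alone; adjusted p = 1.90e-06, adjusted p = 0.386 with an estimated correlation). The adiponectin gene Adipoq changed by -0.96 ± 0.134. Macrophage and Langerhans cell genes fell at 9 of 14 (10 adjusted over the list alone; adjusted p = 5.10e-06, adjusted p = 0.470 with an estimated correlation). The class II antigen gene H2-Ab1 changed by -0.61 ± 0.0955. Dermal fibroblast genes fell at 7 of 12 (7 adjusted over the list alone; adjusted p = 0.00144, adjusted p = 0.539 with an estimated correlation). The collagen gene Col1a1 changed by -0.79 ± 0.151. Glucocorticoid response genes rose at 10 of 19 (12 adjusted over the list alone; adjusted p = 2.90e-04, adjusted p = 0.633 with an estimated correlation). Zbtb16 rose by 1.22 ± 0.304. Basal keratinocyte genes rose at 6 of 10 (6 adjusted over the list alone; adjusted p = 0.0104, adjusted p = 0.431 with an estimated correlation). The epidermal factor gene Trp63 rose by 0.26 ± 0.0667. By limma on RPKM values 1 of the 10 basal keratinocyte genes passed. Fatty acid and triglyceride synthesis rose at 2 and fell at 11 of 25 (15 adjusted over the list alone; adjusted p = 0.00432, adjusted p = 0.633 with an estimated correlation). Ribosomal protein and biogenesis genes rose at 1 and fell at 12 of 30 (13 adjusted over the list alone; adjusted p = 0.0104, adjusted p = 0.622 with an estimated correlation), and 6 passed by limma on RPKM values. S phase genes fell at 6 of 26 and mitosis genes at 4 of 25 (9 and 3 adjusted over the list alone; adjusted p = 0.00432 in each, adjusted p = 0.744 with an estimated correlation). Lymphocyte genes fell at 3 of 9 and endothelium genes rose at 4 of 12 (4 and 4 adjusted over the list alone; adjusted p = 0.0075 and 0.0219, adjusted p = 0.371 and 0.583 with an estimated correlation).

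Smaller calls in MD against ED were oxidative phosphorylation (4 of 29 lower), endoplasmic reticulum chaperones (1 of 18 higher, 5 lower), the clock list (5 of 21 higher, 1 lower), neutrophil and mast cell genes (3 of 9 lower) and antioxidant genes (1 of 20 higher, 5 lower). Members adjusted over the list alone were 4, 6, 6, 3 and 7 in this order. By camera they had adjusted p = 0.0267, 0.0341, 0.0393, 0.0393 and 0.0462 (adjusted p = 0.798, 0.761, 0.555, 0.622 and 0.555 with an estimated correlation). By limma on RPKM values 2 oxidative phosphorylation, 3 chaperone and 4 cholesterol genes passed. Lists without a camera call were p53 and UV damage (5 higher and 1 lower of 18), cholesterol (2 and 6 of 25), fasting (6 and 5 of 27), FOXO (7 and 3 of 26), and glycolysis genes (7 and 3 of 19). Likewise without one were immediate early (2 and 5 of 20), sebocyte (2 and 4 of 14), nerve (2 and 1 of 10) and differentiated keratinocyte genes (1 and 1 of 16). The same holds for heat shock and thermogenic (1 higher each, of 20 and 7), interferon and melanocyte (1 lower each, of 26 and 8), and hair and red blood cell genes, none of which passed edgeR's test. In total 3608 genes differed between MD and ED, 1755 higher and 1853 lower. With muscle and adipocyte list means as covariates 0 passed by edgeR, and the fitted change of Adipoq turned to 0.03.

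**Figure D5:**
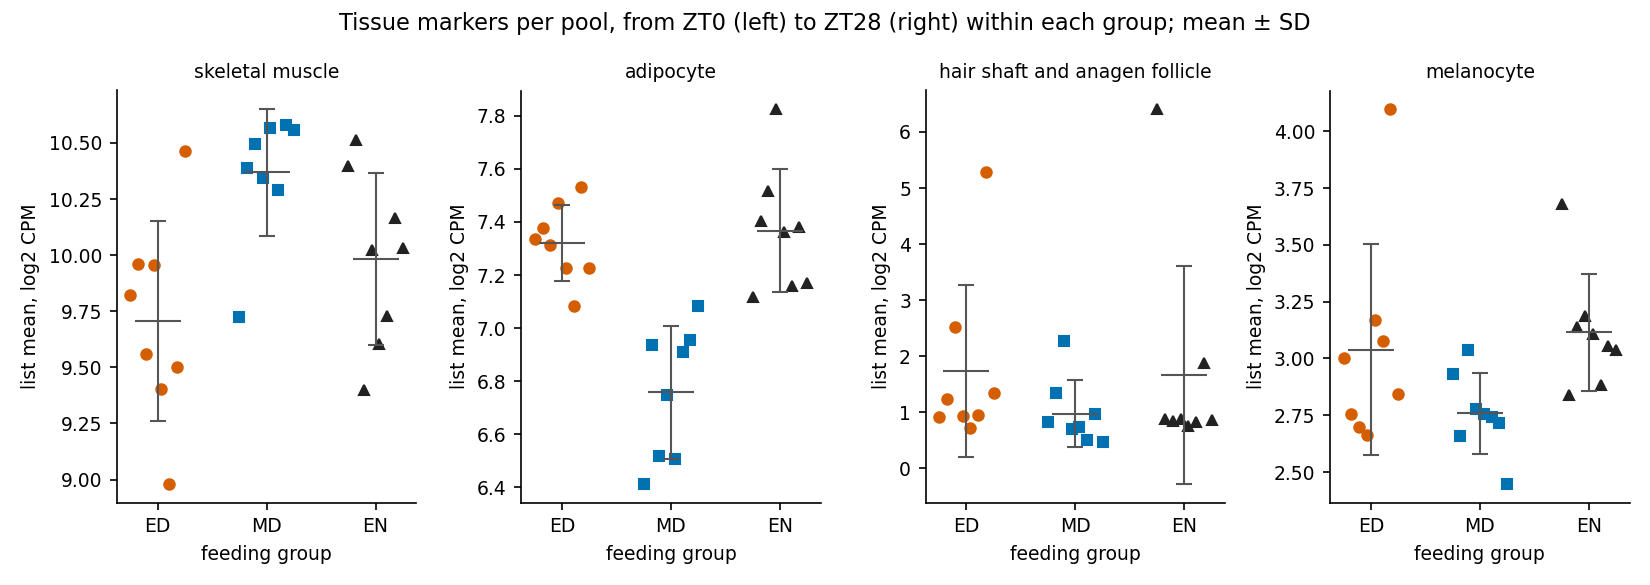
Mean log2 CPM of the skeletal muscle, adipocyte, hair shaft and anagen follicle, and melanocyte lists in each pool of ED, MD and EN, from ZT0 on the left to ZT28 on the right within a group, with the group's mean ± SD. Muscle genes average 10.37 in MD against 9.71 in ED and 9.98 in EN, and the ED ZT24 and EN ZT0 pools lie above the other pools for hair and melanocyte genes.

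Between EN and MD 4748 genes differed, 2492 higher and 2256 lower in EN. Both this and the former comparison use the MD pools. Myh7 rose by 3.59 ± 0.401 and Myl2 by 2.97 ± 0.427 in EN. Nnat, the imprinted neuronatin gene, rose by 2.61 ± 0.448, while Ankrd1 differed by -2.56 ± 0.469. Adipocyte genes rose at 11 of 14, macrophage genes at 11 of 14 and fibroblast genes at 8 of 12 (11, 13 and 8 adjusted over the list alone). Adjusted p by camera in this order was 4.74e-07, 2.6e-06 and 0.00432 (adjusted p = 0.386, 0.445 and 0.555 with an estimated correlation). Muscle genes fell at 11 of 20, basal keratinocyte genes at 7 of 10, glucocorticoid response genes at 10 of 19 and clock genes at 9 of 21 (14, 7, 12 and 10 adjusted over the list alone). Adjusted p by camera in this order was 4.85e-05, 0.00432, 0.00542 and 9.12e-04 (adjusted p = 0.633, 0.386, 0.744 and 0.386 with an estimated correlation). Oxidative phosphorylation rose at 19 of 29 (20 adjusted over the list alone; adjusted p = 1.45e-06, adjusted p = 0.597 with an estimated correlation). Of its respiratory chain genes Cox7a2 rose by 0.73 ± 0.105 and Ndufa1 by 0.55 ± 0.0850. By limma on RPKM values 2 members passed. Ribosomal protein and biogenesis genes rose at 14 and fell at 3 of 30, interferon response genes rose at 7 of 26, lymphocyte genes at 4 of 9, and antioxidant genes rose at 8 and fell at 1 of 20 (17, 6, 4 and 10 adjusted over the list alone). Adjusted p by camera in this order was 0.00542, 0.028, 0.0391 and 0.0393 (adjusted p = 0.583, 0.761, 0.470 and 0.555 with an estimated correlation). Ribosomal protein members passing by limma on RPKM values were 6, interferon members 2, basal keratinocyte members 4 and fibroblast members 5.

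Between EN and ED no gene passed edgeR's test of mean level (961 at an unadjusted p under 0.05, DESeq2 6, limma on RPKM values 0). Camera called 9 lists, of which oxidative phosphorylation was higher in EN (adjusted p = 2.25e-11, adjusted p = 0.386 with an estimated correlation). Of its 29 members 8 had an unadjusted p under 0.05, and 1 passed adjusted over the list alone. Muscle, interferon, fasting, endothelium and adipocyte lists were higher and clock, fatty acid and S phase lists lower in EN by camera. In this order they had adjusted p = 1.85e-07, 0.00164, 0.00542, 0.0123, 0.0471, 0.00144, 0.00542 and 0.0393 (adjusted p = 0.555, 0.583, 0.633, 0.555, 0.657, 0.393, 0.633 and 0.798 with an estimated correlation).

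Other properties of the libraries moved with the groups. Small structural RNAs took 8.21 ± 1.74% of exon counts in ED, 4.77 ± 1.88% in MD and 8.86 ± 0.937% in EN, and intron counts per exon count were 0.666 ± 0.0808, 0.704 ± 0.0663 and 0.603 ± 0.0273 (SD, n = 8 each). The L numbers in the library code run with the groups, and within each group with sampling time. L1 holds MD ZT0 to ZT8 and L2 MD ZT12 to ZT20. L4 holds ED ZT4 to ZT12 and L5 ED ZT16 to ZT24, and L7 holds EN ZT8 to ZT16 and L8 EN ZT20 to ZT28. An effect of the L number could therefore be taken for part of a rhythm, with a phase that differs between groups. L3 holds MD ZT24, MD ZT28 and ED ZT0, and on a scale where the other ED pools are 0 and the other MD pools 1 over 3221 genes, these stood at 0.824, 0.979 and 0.359. L6 holds ED ZT28, EN ZT0 and EN ZT4, which stood at 0.355, 0.0868 and 0.378 on the same scale, and no L number holds both EN and MD. With the L number as a random block 3129 genes differed between MD and ED and 4307 between EN and MD.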

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

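The tests of explanations and the counts over other groupings of the samples in this part were chosen only after the results were seen, whereas the tests of different rhythms were planned.

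Single pools that lay far from the other 7 of their group were looked for with Dixon's ratio (the gap to the nearest pool over the whole range) against its critical value, over 37 measures and 111 group tests. There were 9 such values, from 6 pools, where chance gives about 1 in 20 group tests, or 5.55. Exon counts of EN at ZT20 were high (ratio 0.72; 26316851 counts). Heat shock genes were high in ED at ZT28 (ratio 0.533; list mean 6.88, next pool 6.62, log2 CPM). In MD at ZT0 glycolysis genes (ratio 0.703; 6.83, next 7.23) and skeletal muscle genes (ratio 0.661; 9.73, next 10.29) were low. Endothelium and pericyte genes were high in MD at ZT16 (ratio 0.702; 5.94, next 5.71). Hair shaft and anagen follicle genes were high in ED at ZT24 (ratio 0.606) and in EN at ZT0 (ratio 0.802), and melanocyte genes were high in the same pools (ratios 0.647 and 0.584).

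The first pattern weighed is these hair keratins. Hair list means were 5.29 in the ED ZT24 pool and 6.41 in the EN ZT0 pool, against a median of 0.90 over the 24 pools and 2.52 in the next highest. The other 4 pools of ZT0 and ZT24 ranged from 0.82 to 1.88, so this clock time did not come with such high values in each pool. They lay below the midpoint of 3.10 between the pair and the median, but so did every other pool. The comparison with the midpoint could not come out otherwise, and it does not exclude time of day as a part of the cause. Growing follicles in some of the pooled mice may be the source, although the labels give telogen. The melanocyte list was also highest in this pair of pools, at 4.10 and 3.68 (next 3.19), but its members disagree. The pigment genes Dct, Tyr, Tyrp1 and Pmel, 4 of 8 members, lay above each of the other 22 pools in both, whereas Mitf (5.74 and 5.89, highest other 6.30), Sox10 (3.45 and 3.17, highest other 3.69) and Kit (4.18 and 4.14, highest other 4.31) did not. The melanocyte list had been seen to stand out before it was taken up, so growing follicles stay open. Both pools were also high in mitosis genes, and the feeding group was not tested as a cause.

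The second pattern is that the MD pools stood apart in mean level. The L numbers run with the groups: within L3 the gap between the MD pools and the ED pool was 0.543 of the gap outside it over 3221 genes, but ED pools ranged from -0.268 to 0.359 on this scale, so the library code and the feeding group cannot be told apart from a single ED pool. More muscle and less fat in the MD pools may account for much of it: slopes on both list means within ED and EN predicted a median of 0.720 of the change between MD and ED over 3580 genes, with an equal sign in 84.1%. With both list means as covariates 0 genes passed; the median size of the change went from 0.36 to 0.15 and its median standard error from 0.0937 to 0.204, since the means share an R² of 0.733 with membership in MD, and 68.7% of the called genes kept their direction. Skin taken further back on the body is a candidate explanation as well. Of Hox genes of groups 5 to 10, 11 of 16 were higher in MD than in ED, against 0 of 10 of groups 1 to 4 (Fisher's exact p = 7.23e-04). This test takes the genes as independent, although they were measured in the same pools. Among the 11, Hoxa6, Hoxa9, Hoxa10 and Hoxb9 were low, with mean log2 CPM of -0.01, 0.03, 0.22 and 0.49. The others of the 11 ranged from 1.84 (Hoxb7) to 3.02 (Hoxc6). Feeding in MD itself stays open and was not separable in this design.

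The third pattern is the clock. If the sampling times of a whole group were wrong, all rhythms would move alike, but the mitosis list differed by -2.73 ± 1.37 h between MD and ED and by 0.44 ± 0.775 h between EN and ED. These values cover all 25 members, of which few were rhythmic in MD. The clock shifts minus these values were -4.99 ± 1.41 h and -3.78 ± 0.972 h. Over the members rhythmic in both groups adjusted over the list alone (7 and 18), the mitosis shifts were -2.29 ± 0.641 h and 0.615 ± 0.517 h. The clock shifts minus these were -5.43 ± 0.736 h and -3.95 ± 0.782 h. This excludes wrong times as the whole cause, and without the ED ZT24 and EN ZT0 pools the mitosis values were -2.43 ± 1.52 h and 0.73 ± 0.776 h. With the muscle and fat list means as covariates the clock shifts were -7.70 h and -3.58 h. This speaks against an added linear effect of both means. Such terms would not remove a mix of tissues whose clocks differ in phase, so muscle and fat content is not excluded as a cause. A shift of the clock of the skin by the time of feeding remains a hypothesis, and the library code was not tested as a cause of it.

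Rhythms differed between feeding groups at 55 genes (MD and ED), 63 genes (EN and ED) and 55 genes (EN and MD) by the test of the difference itself. Rhythms also appeared in reads outside the main measurement, for which there are no control samples. Intron rows held 66 rhythmic genes in ED, 122 in MD and 131 in EN of 14585 tested, of which 32, 33 and 53 were also rhythmic in exon rows. Antisense rows held 21, 46 and 45 of 7729 tested, of which 0, 1 and 3 were also rhythmic in exon rows by edgeR.

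Each count was compared with 100 groupings of the libraries, the real one included. Sampling times shuffled within groups gave at most 13, 13 and 18 rhythmic genes against 113, 148 and 166, so that chance can be excluded (1 of 100 as high in each). The shuffles also break the run of L numbers with sampling time, so they do not address an effect of the library code. Feeding labels shuffled within times gave at most 15 genes after food against 762, and in mean level at most 1662 against 3608 for MD and ED and 34 against 4748 for EN and MD (1 of 100 in each). For EN and ED the real count of 0 was reached by 100 of 100, and another grouping gave 1027. Different rhythms were as many in 4 of 100 groupings for MD and ED (highest other 1474) and for EN and ED (1888). For EN and MD it was 5 of 100 (1248). These shares lie close together and were not adjusted over the 3 pairs, so chance cannot be excluded for any pair. Genes following food and light were as many in only 3 of 100, but the highest other counts were 189 and 173, so chance is not excluded. Shuffled feeding labels also carry the level difference of MD into the error, which can lower their counts. Those few groupings that call far more genes than the real one point to a structure of the samples, whose nature was not tested.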

How the results depend on the processing

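The alternatives without the ED ZT24 and EN ZT0 pools, without small structural RNA rows, without MD, on intron rows and, for the clock phase, with tissue covariates were chosen only after the results were seen, and the others were planned. Of 573 recomputed counts, phase differences and list tests, 460 kept their direction and stayed within 1.5 times the value or on the same side of the threshold. Among the 573, the food count with sampling time as a block only repeated the main fit. The shift of the clock was -8.01 to -7.53 h for MD minus ED, -3.82 to -3.10 h for EN minus ED and 3.98 to 4.56 h for EN minus MD with a library or time left out. Without ZT8 in either group the value for EN minus MD was 4.46 h but its exact permutation p of 0.0781 no longer passed (0.00781 with all times), and the cause was not tested. On intron rows the shifts were -7.48, -3.15 and 3.92 h, and on deposited RPKM values -7.79, -3.36 and 4.40 h.

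Counts of rhythmic genes moved with several settings. For ED (113) they were 394 with DESeq2, 24 without the second day, 58 with the library code as a block, 74 with the group alone, 38 with an added harmonic of 12 h, 61 without the ED ZT24 and EN ZT0 pools and 66 on intron rows. For MD (148) the DESeq2 test gave 494, no second day 78, the group alone 23 and the added harmonic 84. For EN (166) no filter gave 257, DESeq2 348, tissue covariates 92, no second day 64, the library code 94, the group alone 298, the added harmonic 107 and leaving out both pools 98. With 1 library left out, ED ranged from 25 to 153 (ED without ZT4 63, ZT8 41, ZT12 25, ZT16 75, ZT20 58, ZT24 59), MD from 51 to 200 (MD without ZT0 91, ZT4 51, ZT12 67, ZT28 60) and EN from 43 to 191 (EN without ZT0 89, ZT12 43, ZT16 83, ZT24 101). The cause of these changes was not tested.

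Different rhythms between MD and ED (55) were 210 with DESeq2 and 16 without the second day. Between EN and ED (63) they were 95 with no filter, 271 with DESeq2, 140 with tissue covariates, 20 without the second day, 34 with the added harmonic and 130 without MD. Between EN and MD (55) they were 250 with DESeq2, 22 without the second day, 31 with the library code and 34 without the ED ZT24 and EN ZT0 pools. With 1 library left out the ranges were 29 to 70 (MD without ZT28 36, ED without ZT4 29 or ZT16 36), 33 to 122 (MD without ZT0 95 or ZT16 122, EN without ZT12 36 or ZT16 33) and 22 to 72 (MD without ZT4 34, ZT8 35 or ZT12 34, EN without ZT0 32, ZT12 22, ZT16 27 or ZT28 33). With sampling time as a replicate block they were 71, 136 and 95, and for mean levels 3102, 0 and 4521. For food the fit kept time of day as its term and repeated the main result of 762 genes, so the block was not tested there. The numbers of the libraries are sampling times and do not pair animals: deviations of libraries with the same number correlated at -0.0613 to 0.175 for MD and ED, -0.0508 to 0.245 for EN and ED and -0.153 to 0.195 for EN and MD, and 1, 2 and 1 of 8 correlated best with their own number. The block changed no count of mean levels by over 1.5 times.

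In mean level, tissue covariates left 0 genes between MD and ED (3608), 1 between EN and MD (4748) and 1 between EN and ED (0), where DESeq2 gave 6. Under these covariates the log2 change of Adipoq (0.0284), Cdk1 (9.05e-04), Defb8 (0.0664), Dst (-0.0776), Lyz2 (0.33), Myh1 (-0.15) and Retn (0.26) between MD and ED and of Adipoq (-0.0189) and Nnat (-0.81) between EN and MD turned its sign. Muscle and fat genes are themselves part of the covariates, and for the others the cause was not tested. With 1 library left out the counts ranged from 1981 to 3943 (MD without ZT16 1981, ED without ZT12 2382), 0 to 0 and 3167 to 4996. Genes after food (762) were 177 with tissue covariates, 373 without the second day, 344 without pools at the hour of opening, 451 without a term for time of day, 391 with a cosine and sine of hours since food and 345 without MD, where 62.6% were higher against 49.3%. With 1 library left out they ranged from 302 to 1038 (MD without ZT4 397 or ZT12 353, ED without ZT20 417 or ZT28 302, EN without ZT8 314, ZT12 383 or ZT20 315).

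Genes following food (58) were 244 with DESeq2, 17 without the second day and 24 with stricter thresholds. Those following light (92) were 161 with no filter, 239 with DESeq2, 38 without the second day, 51 with the library code and 39 with stricter thresholds, and those departing from both frames (61) were 190, 20 and 39 with DESeq2, without the second day and with the library code. With 1 library left out the ranges were 33 to 83 (MD without ZT4 36, EN without ZT12 33 or ZT16 37), 36 to 104 (ED without ZT8 56 or ZT12 36, EN without ZT12 60) and 31 to 62 (MD without ZT4 33 or ZT28 36, ED without ZT4 38 or ZT12 40, EN without ZT12 31 or ZT16 38). List calls of camera with an estimated correlation were 0 for each contrast, against 17 (MD and ED), 9 (EN and ED), 12 (EN and MD) and 16 (food). By fry they were 10, 0, 9 and 8, and with tissue covariates 9 for MD and ED and 5 for EN and ED.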

Other observations

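The tests in this part were all chosen only after the result was seen.

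A hypothesis drawn from the intron rows is that unspliced RNA of clock genes peaks before their spliced RNA, as it would if the rhythm starts with transcription. Over clock genes rhythmic in both row types, intron rows peaked at -0.873 ± 0.220 h relative to exon rows in ED (10 of 10 genes earlier), at -0.658 ± 0.0385 h in MD (9 of 10) and at -0.764 ± 0.0614 h in EN (16 of 17; jackknife standard error over 8 times). An exact permutation test that swapped intron and exon values within sampling times, after the mean of each row was removed, gave p = 0.00781 in each group (adjusted p = 0.00781), the smallest it can give. Its statistic, the summed squared difference of cosine and sine terms, answers to amplitude as well as to lag. This p is therefore not a test of the lag alone. With the means left in, p was 0.984 in ED, 1 in MD and 1 in EN, as swaps then mix the difference in level into the curves. The intron and exon rows come from the same libraries, so an error in sampling time cannot give this lag, whereas reads of overlapping transcripts in introns could add to it.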
